A study of Homo sapiens with 18 samples.

How the data were processed

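Expression was measured on Illumina bead arrays in 18 samples of human adipose-derived stem cells, 6 groups of 3, with 1 array per sample. Per the labels, RNA was extracted with an Aurum kit, checked on a Bioanalyzer and labelled with biotin using an Ambion MessageAmp kit. GenomeStudio and lumi are named as processing tools, with versions not given in the sources used here. The deposited raw table gives, per the file headers, an average bead signal (intensity) for each probe and array, not normalised between arrays. Beside each signal, per the file headers, it gives a detection p-value against the negative control beads. The processed values deposited by the authors are on a log2 scale and quantile normalised, which was read from the values, since every array holds the same sorted numbers with a median of 6.36. Each processed array had a rank correlation of 1 with the raw signals of the same sample. The 12 empty columns of the raw table were left out, and 0 value columns could not be mapped to a sample.

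The raw signals were used. They were background corrected and quantile normalised with neqc (offset 16, background estimated from the detection p-values) in limma 3.58.1 under R 4.3.3, with statmod 1.5.0 for estimated correlations. Probes with a detection p under 0.01 on at least 3 of the 18 arrays were kept (19070 of 47220). Probes were paired with gene names through the reference annotation. Of all probes, 30107 matched 1 gene, 8 matched several and 17105 (36.2%) matched none, and 30068 of the names were matched by gene number. The kept probes included 15060 with 1 gene name, which gave 11255 genes, and 4010 without a single gene name. The brightest kept probe stood for each gene, a choice that applied to 3066 genes. The files name no genome build, so no coordinates are given.

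A linear model with 1 mean per group was fitted to all 18 arrays with lmFit and eBayes (12 residual and 3.55 prior degrees of freedom). Each siKLF group was compared with siCTRL, and with the mean of the other 4 siKLF groups to see what sets a knockdown apart. A moderated F test over the 5 comparisons with siCTRL asked which genes differ among the groups. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Every KLF probe was also fitted without the detection filter, with adjustment over the 5 probes of the targeted genes (2 of KLF4 and 1 each of KLF9, KLF16 and KLF17). Gene lists written from textbook knowledge were tested with camera at a preset correlation of 0.01, adjusted over 240 tests (48 lists with at least 5 genes tested, 5 comparisons). Of 52 lists written, 48 could be tested, and 982 of 1264 list entries were genes tested. Camera with an estimated correlation and fry, which asks whether a list moves on balance 1 way without comparing it with other genes, were run beside it. Fry called 23, 28, 20, 27 and 21 lists in siKLF4, siKLF9, siKLF11, siKLF16 and siKLF17. No list called against siCTRL had a median and a camera test of different sign. Gene lists, tests, thresholds, alternatives and the naming rule were fixed before the data were examined. Camera on the contrasts between knockdowns, a background covariate and a fit on lower-background arrays were added after the data were seen.

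Named genes followed a rule. For each siKLF group against siCTRL these were the targeted genes, the 10 genes with the largest log2 fold change in each direction among those called whose 3 siKLF arrays all lay above or all below the 3 control arrays, and the 4 members with the smallest p of each called list. For each group against the other 4 they were the 5 largest differences each way, with the group's arrays outside the range of the other 12. For all knockdowns together they were the 10 genes with the smallest F-test p among those called in the same direction in at least 4 comparisons. Names were shortened only by taking the first in that order. Sex-linked marker genes were left out. A gene undetected on all arrays of 1 group is given only as a lower bound of the fold, against the lowest detected signal of each of those arrays (or the gene's own signal there where that was higher), with no fold where that bound was under 1. Against the other 4 siKLF groups, each of these that was undetected on all its arrays enters the mean at that bound. The adjusted p beside a bound comes from the limma fit on all values, those below detection included, and does not test the bound.

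The procedure was tested on simulated data made for siKLF17 against siCTRL, with 11255 genes of which 200 changed, in 5 runs. With arrays as noisy as measured it recovered 66.9% of changes of 1.5-fold, 90.4% of 2-fold and 99.4% of 4-fold, and 10.1% of its calls were false. With arrays of equal noise 5.41% were false, and with array weights 5.19%. A simulated change in the interferon response list was called in 5 of 5 runs, and 0 of 1195 other list tests passed. Genes varied independently in these runs, so they do not show how often lists of co-regulated genes are called falsely.

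Alternatives changed 1 choice at a time. They were no background correction, an offset of 50, median scaling in place of quantile normalization, the authors' processed values, no detection filter or detection on all 18 arrays, the mean of a gene's probes, all kept probes, array weights, the replicate number as a block, only the 2 groups compared, a change of at least 1.5-fold, and leaving out each array in turn. Other splits of the arrays into groups of the same sizes were refitted in the same way. A block for the array chip was not run, because the column names give no chip. Figures were drawn from the same values.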

Results

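RNA from human adipose-derived stem cells (hADSC), mesenchymal cells of fat tissue that can form adipocytes, bone and cartilage cells in culture, was measured on Illumina expression arrays. Purchased cells were grown in MesenPRO RS medium in 6-well dishes and received a small interfering RNA (siRNA) against 1 member of the Krüppel-like factor (KLF) family of transcription factors. RNA was collected 2 days later. There were 6 groups of 3 arrays, 18 in all, named siCTRL (scrambled siRNA), siKLF4, siKLF9, siKLF11, siKLF16 and siKLF17. The labels number the replicates 1 to 3 without saying whether these were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

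The table held 47220 probes, and 11255 genes were tested. On 17 arrays, 16913 to 18145 probes were detected above background and the median raw signal was 83.1 to 185. On siCTRL replicate 2, 13962 probes were detected and the median raw signal was 300.5. Log2 values of that array correlated at 0.984 across genes with each of the other controls, and those of siCTRL replicates 1 and 3 at 0.992 with each other. All siKLF groups share these 3 controls, so values without siCTRL replicate 2 are given where leaving it out ends the call of a gene or list named below.

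The first question was whether each siRNA lowered its target. KLF4 (probe ILMN_2137789) had a normalised log2 intensity of 11.12 ± 0.17 (SD, n = 3) in siCTRL and 9.12 ± 0.13 (SD, n = 3) in siKLF4, 25.0% of the control level. The log2 fold change was -2.00 (SE 0.12), with a limma adjusted p of 1.43e-10 over the 5 probes of the targeted genes. A further KLF4 probe (ILMN_1779857) fell by 1.90 on the log2 scale. KLF9 (probe ILMN_1778523) went from 12.34 ± 0.07 (SD, n = 3) in siCTRL to 9.92 ± 0.15 (SD, n = 3) in siKLF9, 18.8% of the control level. Its log2 fold change was -2.41 (SE 0.09), with a limma adjusted p of 1.05e-13. KLF16 (probe ILMN_1770451) and KLF17 (probe ILMN_1744220) were detected on 0 of 18 arrays, with lowest detection p-values of 0.353 and 0.170, so no fold is given and their knockdown was not measurable here. KLF11 had no probe under that name in the annotation used, so its level was not analysed here.

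Among the targeted genes in the other groups, KLF4 was higher in siKLF9 (0.36 ± 0.11, adjusted p = 0.0279) and lower in siKLF11 (-0.37 ± 0.11, adjusted p = 0.0439), both as log2 fold change ± SE with adjustment over all genes. The KLF4 call in siKLF9 was lost without siCTRL replicate 2 (adjusted p = 0.114), siCTRL replicate 3 (0.0604), siKLF9 replicate 2 (0.104) or siKLF9 replicate 3 (0.0546). The KLF4 call in siKLF11 was lost without siCTRL replicate 1 (adjusted p = 0.155), siCTRL replicate 3 (0.0598), siKLF11 replicate 2 (0.0963) or siKLF11 replicate 3 (0.156). The replicate number as a block ended that call too (limma adjusted p = 0.0534). Both were also lost under median scaling (0.47 with adjusted p = 0.174, and -0.32 with adjusted p = 0.607), without a detection filter (adjusted p = 0.0543 and 0.0834), with array weights (0.0906 and 0.0536), in a fit of the 2 groups compared (0.0789 and 0.148) and on lower-background arrays, where each of these groups keeps 1 array (0.40 with adjusted p = 0.177, and -0.48 with adjusted p = 0.210). KLF9 did not pass in siKLF4 (-0.10, adjusted p = 0.397), siKLF11 (0.21, adjusted p = 0.105), siKLF16 (-0.00297, adjusted p = 0.986) or siKLF17 (-0.21, adjusted p = 0.0905) over all genes, but over the 5 probes of the targeted genes it passed as higher in siKLF11 (adjusted p = 0.0476).

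**Figure D1:**
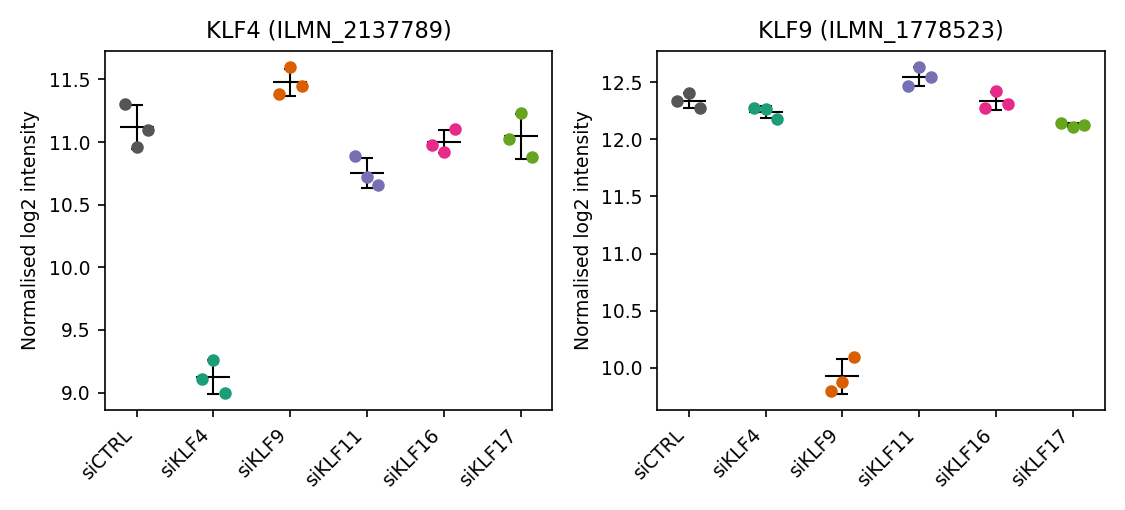
Normalised log2 intensity of KLF4 and KLF9 on each of the 18 arrays, by group; points are arrays, the horizontal bar is the group mean and the error bar is the SD of 3 arrays. KLF4 averaged 9.12 in siKLF4 against 11.12 in siCTRL, and KLF9 averaged 9.92 in siKLF9 against 12.34 in siCTRL.

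At adjusted p under 0.05, genes called higher and lower numbered 1528 and 1267 in siKLF4 (24.8% of those tested), 1578 and 1476 in siKLF9 (27.1%), 678 and 741 in siKLF11 (12.6%), 1212 and 1140 in siKLF16 (20.9%) and 765 and 789 in siKLF17 (13.8%). Changes of at least 1.5-fold were fewer, with 962, 1087, 542, 776 and 522 genes in that order. All 3 siKLF arrays lay outside the range of the 3 control arrays for 2666, 2874, 1368, 2255 and 1516 of the called genes. Over all genes tested this held for 4048, 4258, 2952, 3964 and 3427, where chance gives 10%. Without siCTRL replicate 2 the counts were 2236, 2481, 993, 1796 and 987, of which 2021, 2218, 891, 1573 and 884 were called in the same direction with all arrays. The siKLF11 count was 870 without siKLF11 replicate 3, and the siKLF17 count was 1003 without siKLF17 replicate 2 and 975 without siKLF17 replicate 3.

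The share of called genes that were higher depended on the scaling between arrays. It was 54.7%, 51.7%, 47.8%, 51.5% and 49.2% in siKLF4, siKLF9, siKLF11, siKLF16 and siKLF17 under quantile normalization, and 80.8%, 73.4%, 72.0%, 73.7% and 68.4% under median scaling of the log2 values. Median scaling called 994, 1062, 339, 521 and 269 genes. Under it the median of all genes tested stood at 0.16 in siKLF4, 0.16 in siKLF9, 0.07 in siKLF11, 0.08 in siKLF16 and 0.09 in siKLF17, against 0.02, 0.03, -0.000348, 0.01 and 0.01 under quantile normalization. Small changes below are therefore relative to a typical gene. Genes named below that did not pass under median scaling are listed with each comparison.

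**Figure D2:**
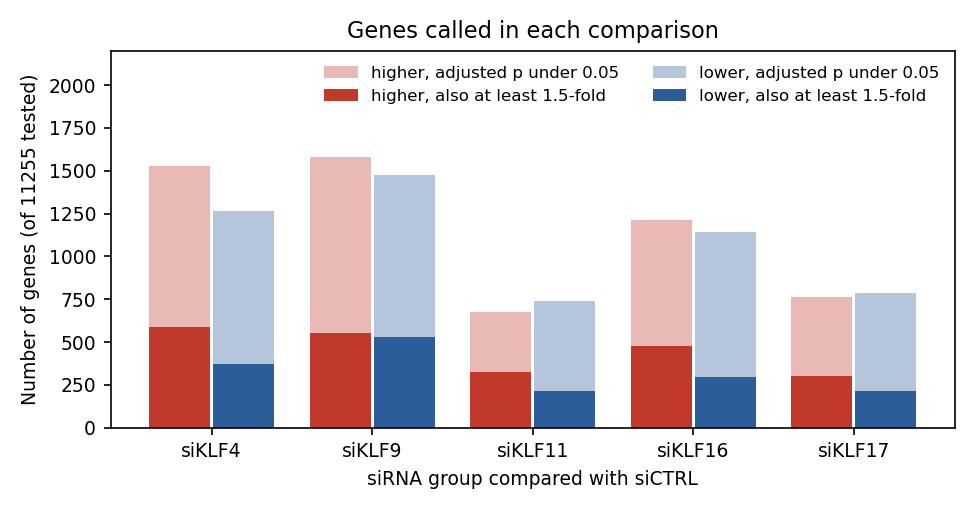
Number of genes called higher (red) and lower (blue) in each siKLF group against siCTRL at limma adjusted p under 0.05 (pale bars) and also changed at least 1.5-fold (dark bars). siKLF9 had 3054 called genes and siKLF11 had 1419.

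The siKLF4 comparison asked which genes differ after transfection of the siRNA against KLF4, whose level fell. In this and the other comparisons, effects of a siRNA on other transcripts are not separated from those of a lower target. Values below are log2 fold changes ± SE from limma with 3 arrays per group, and each of the genes named with the largest changes had its 3 siKLF arrays all above or all below the 3 control arrays. Where a gene was detected on no array of 1 group, only a lower bound is given, taken against the lowest detected signal of those arrays. The adjusted p beside it is that of the fit, which uses values below detection, and does not test the bound. The chemokines CCL8 (2.52 ± 0.15, adjusted p = 2.82e-08) and CCL7 (2.35 ± 0.13, adjusted p = 1.59e-08), which attract monocytes, rose in siKLF4. RASL11B (2.36 ± 0.22), a small GTPase, and COL22A1 (2.25 ± 0.14), a collagen, also rose and were each detected on 2 of 3 control arrays. TRIL (2.12 ± 0.12), a partner of Toll-like receptors, CTXN1 (2.11 ± 0.13) and the granule protein SCG2 (2.01 ± 0.12) rose from a detected level. The RNA-binding protein IGF2BP3 (2.10 ± 0.14) was detected on 1 of 3 control arrays. CITED4 was at least 2.10-fold higher (adjusted p = 1.28e-05) and CFAP206 at least 1.63-fold higher (adjusted p = 1.26e-05).

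KLF4 itself (-2.00 ± 0.11, adjusted p = 1.72e-08) had the lowest value of the named genes with a fitted value given here. PCP4, a calmodulin-binding protein detected on 2 of 3 control arrays, was at least 1.37-fold lower (adjusted p = 1.20e-07). HAPLN1 (-1.91 ± 0.13), which links hyaluronan to proteoglycan, and PRG4 (-1.84 ± 0.12), the joint lubricant lubricin, fell. PTGIS (-1.74 ± 0.12), which makes prostacyclin, IMMP2L (-1.62 ± 0.08), a mitochondrial peptidase, and CCN5 (-1.58 ± 0.13), a secreted matricellular protein, fell as well. ERLIN2 fell on its brightest probe (-1.58 ± 0.08), but neither of its 2 other probes moved the same way. SLC16A9 was at least 1.80-fold lower (adjusted p = 3.22e-05) and PI16 at least 2.18-fold lower (adjusted p = 0.00433).

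Camera, a limma test of whether a list moves against all other genes, called 9 of 48 lists in siKLF4, of which 5 held with an estimated correlation. P-values for lists were adjusted over 240 tests, medians are of log2 fold changes, and the median of every called list moved in the called direction on 3 of 3 siKLF arrays. Each array was set against the same mean of the controls, and many lists not called also moved 1 way on 3 of 3 arrays. The 3 arrays are therefore not separate support for a call. In the NF-kB and inflammation list of 27 genes, 19 rose and 1 fell, 21 and 1 adjusted over the list alone, with a median of 0.67 (0.62 with undetected genes at their bound), adjusted p = 2.66e-10 and adjusted p = 0.0188 with an estimated correlation. CXCL8 (1.69 ± 0.10), which attracts neutrophils, has the smallest p in it after CCL7. In the cholesterol biosynthesis list of 20 genes, 13 rose and 1 fell, 15 and 1 adjusted over the list alone, with a median of 0.43, adjusted p = 1.61e-06 and adjusted p = 0.0191 with an estimated correlation. DHCR7 (0.82) and IDI1 (0.77), enzymes of sterol synthesis, rose, while INSIG1 (-0.68), which restrains it, fell. In the amino acid and ATF4 list of 28 genes, 0 rose and 15 fell, 0 and 20 adjusted over the list alone, with a median of -0.33, adjusted p = 2.05e-06 and adjusted p = 0.0127 with an estimated correlation. SLC7A5 (-1.22 ± 0.09), a transporter of large amino acids, and CTH (-0.64), which makes cysteine, fell. In the replication histone list of 11 genes, 9 rose and 1 fell, 9 and 1 adjusted over the list alone, with a median of 0.58 (0.54 with undetected genes at their bound), adjusted p = 2.60e-05 and adjusted p = 0.00882 with an estimated correlation. H2AC6 (1.08) and H2BC5 (1.01) rose, though probes of near-identical histone genes may cross-hybridise. In the p53 target list of 24 genes, 8 rose and 0 fell, 8 and 0 adjusted over the list alone, with a median of 0.14, adjusted p = 0.00481 and adjusted p = 0.0386 with an estimated correlation. TP53INP1 (0.82), SESN1 (0.64) and the cell cycle inhibitor CDKN1A (0.62) rose.

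In the S-phase replication list of 39 genes, 1 rose and 11 fell, 1 and 13 adjusted over the list alone, with a median of -0.24 (-0.20 with undetected genes at their bound), adjusted p = 0.000913 and adjusted p = 0.302 with an estimated correlation. PRIM1 (-0.59), a primase subunit, and CDC45 (-0.48), part of the replicative helicase, fell. In the HLA and antigen presentation list of 16 genes, 6 rose and 0 fell, 6 and 0 adjusted over the list alone, with a median of 0.27 (0.23 with undetected genes at their bound), adjusted p = 0.0278 and adjusted p = 0.322 with an estimated correlation. HLA-B (0.80) rose. In the chondrogenesis list of 8 genes, 1 rose and 3 fell, 1 and 3 adjusted over the list alone, with a median of -0.26, adjusted p = 0.0398 and adjusted p = 0.193 with an estimated correlation. PRG4 and HAPLN1 are its strongest members in siKLF4. In the neural marker list of 8 genes, 4 rose and 0 fell, 4 and 0 adjusted over the list alone, with a median of 0.36 (0.10 with undetected genes at their bound), adjusted p = 0.0379 and adjusted p = 0.197 with an estimated correlation. NEFM (1.11), a neurofilament detected on 2 of 3 control arrays, rose. The HLA call in siKLF4 was lost without siCTRL replicate 1 (adjusted p = 0.103), without siKLF4 replicate 1 (adjusted p = 0.0748) or with the mean of a gene's probes (adjusted p = 0.0868). The chondrogenesis call was lost without siCTRL replicate 3 (adjusted p = 0.0760), without a detection filter (median -0.03, adjusted p = 0.126), with probes detected on all 18 arrays (adjusted p = 0.0707) or on lower-background arrays (adjusted p = 0.0655). The neural marker call was lost without siCTRL replicate 2 (adjusted p = 0.0567), without siCTRL replicate 3 (adjusted p = 0.0539), without siKLF4 replicate 1 (adjusted p = 0.0595), without a detection filter (median 0.10, adjusted p = 0.177) or with array weights (adjusted p = 0.0525). Among the genes named for siKLF4, PRIM1 (-0.45, adjusted p = 0.191), CDC45 (-0.33, adjusted p = 0.343), INSIG1 (-0.37, adjusted p = 0.302) and CTH (-0.52, adjusted p = 0.0974) did not pass under median scaling.

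Against the mean of the other 4 siKLF groups, siKLF4 had 2539 genes set apart, 1374 higher and 1165 lower. CTXN1 (2.01 ± 0.11), PDE4B (1.87 ± 0.10), which degrades cyclic AMP, and TRIL (1.86 ± 0.09) stood above the other knockdowns. GJB2 (-1.95 ± 0.06, adjusted p = 1.02e-11), a gap junction protein, KLF4 (-1.95 ± 0.09) and the cell cycle regulator RGCC (-1.88 ± 0.10) stood below. The cholesterol biosynthesis list had 15 of 20 genes higher and 1 lower, with a median of 0.47, adjusted p = 1.89e-06 and adjusted p = 0.0240 with an estimated correlation in this contrast.

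The siKLF9 comparison asked the same of the siRNA against KLF9. NTSR1, the neurotensin receptor, was at least 2.56-fold higher (adjusted p = 3.19e-07), PLXDC1 at least 3.85-fold (adjusted p = 5.83e-07), the transcription factor FOXQ1 at least 2.57-fold (adjusted p = 3.19e-07) and RGS20, a regulator of G-protein signalling, at least 3.13-fold (adjusted p = 6.59e-07). GLDC (2.31 ± 0.23), which cleaves glycine, MAMDC2 (2.03 ± 0.26) and VWCE (1.86 ± 0.28) rose and were each detected on 2 of 3 control arrays. The urea transporter SLC14A1 was at least 1.76-fold higher (adjusted p = 3.58e-06) and CDHR3 at least 1.57-fold higher (adjusted p = 2.10e-06). KRT19 (1.86 ± 0.13, adjusted p = 1.16e-07), a keratin, rose.

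KLF9 (-2.41 ± 0.08, adjusted p = 2.22e-11) and TIMP4 (-2.40 ± 0.12, adjusted p = 2.61e-09), an inhibitor of matrix proteases, fell most in siKLF9 among genes with a fitted value given here. The potassium channel KCNH1 was at least 3.78-fold lower (adjusted p = 3.54e-08). QDPR (-2.12 ± 0.08), which recycles tetrahydrobiopterin, and NBN (-2.09 ± 0.07, adjusted p = 2.22e-11), a DNA repair protein, fell. MBOAT7 (-1.97 ± 0.14), an acyltransferase of phosphatidylinositol, TAF9B (-1.88 ± 0.11) and SUCLA2 (-1.80 ± 0.10), an enzyme of the citric acid cycle, fell. MSI2, detected on 2 of 3 control arrays, was at least 1.72-fold lower (adjusted p = 5.03e-07), and WASHC4 (-1.63 ± 0.18) was detected on 2 of 3 siKLF9 arrays.

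Camera called 7 lists in siKLF9, of which 2 held with an estimated correlation. In the amino acid and ATF4 list of 28 genes, 0 rose and 17 fell, 0 and 20 adjusted over the list alone, with a median of -0.46, adjusted p = 1.08e-09 and adjusted p = 0.00558 with an estimated correlation. CTH (-1.10 ± 0.10), ASNS (-0.81), which makes asparagine, and TRIB3 (-0.83), a stress-induced pseudokinase, fell. In the p53 target list of 24 genes, 14 rose and 2 fell, 17 and 3 adjusted over the list alone, with a median of 0.45, adjusted p = 4.35e-05 and adjusted p = 0.00882 with an estimated correlation. SESN1 (0.95), the death receptor TNFRSF10B (0.66) and BAX (1.23), which opens the mitochondrial membrane in apoptosis, rose. In the G2/M and mitosis list of 54 genes, 13 rose and 1 fell, 13 and 1 adjusted over the list alone, with a median of 0.20, adjusted p = 0.00127 and adjusted p = 0.547 with an estimated correlation. PTTG1 (0.65), which holds sister chromatids together, and CDC25B (0.46), a phosphatase that starts mitosis, rose. The G2/M call in siKLF9 was lost without siCTRL replicate 3 (adjusted p = 0.0636). In the immediate early gene list of 23 genes, 10 rose and 3 fell, 11 and 3 adjusted over the list alone, with a median of 0.35, adjusted p = 0.0130 and adjusted p = 0.208 with an estimated correlation. DUSP5 (0.92), EGR1 (0.99) and DUSP6 (1.12), genes induced by growth factor signalling, rose. In the fatty acid and lipid synthesis list of 17 genes, 0 rose and 6 fell, 0 and 6 adjusted over the list alone, with a median of -0.14, adjusted p = 0.0130 and adjusted p = 0.244 with an estimated correlation. GPAM (-1.01), the first enzyme of triglyceride synthesis, and ME1 (-0.55), which supplies NADPH, fell.

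In the chondrogenesis list of 8 genes, 0 rose and 5 fell, 0 and 5 adjusted over the list alone, with a median of -0.46, adjusted p = 0.0208 and adjusted p = 0.139 with an estimated correlation. HAPLN1 (-1.29) and PRG4 (-1.09) fell. In the myofibroblast and smooth muscle list of 12 genes, 1 rose and 4 fell, 1 and 4 adjusted over the list alone, with a median of -0.20, adjusted p = 0.0422 and adjusted p = 0.317 with an estimated correlation. TPM1 (-0.86) and TAGLN (-0.84), actin-binding proteins of contractile cells, fell. The myofibroblast call was lost without siCTRL replicate 3 (median -0.11, adjusted p = 0.112), without siKLF9 replicate 2 (adjusted p = 0.0584), under median scaling (median -0.05, adjusted p = 0.292), with probes detected on all 18 arrays (adjusted p = 0.0855), with the mean of a gene's probes (adjusted p = 0.0868) or with a background covariate (adjusted p = 0.0520). Among the genes named for siKLF9, ASNS (-0.62, adjusted p = 0.0610), CDC25B (0.57, adjusted p = 0.0921), ME1 (-0.46, adjusted p = 0.141), TPM1 (-0.36, adjusted p = 0.342) and TAGLN (-0.48, adjusted p = 0.173) did not pass under median scaling.

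Against the other 4 siKLF groups, siKLF9 had 3541 genes set apart, 1858 higher and 1683 lower. CCN5 (2.04 ± 0.10) stood above them, and CDHR3 was at least 2.07-fold higher (adjusted p = 6.80e-08). The interferon-induced IFI44L (-2.49 ± 0.16), KLF9 (-2.39 ± 0.06) and TIMP4 (-2.32 ± 0.09) stood below. The NF-kB and inflammation list had 1 of 27 genes higher and 18 lower, with a median of -0.44 (-0.36 with undetected genes at their bound), adjusted p = 2.54e-08 and adjusted p = 0.0391 with an estimated correlation. Against siCTRL that list was not called in siKLF9 (median -0.06) or siKLF17 (0.03). It was called higher in siKLF4 (0.67), siKLF11 (0.77) and siKLF16 (0.65). The p53 target list had 14 of 24 genes higher and 3 lower, with a median of 0.31, adjusted p = 0.00419 and adjusted p = 0.0391 with an estimated correlation.

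The siKLF11 comparison asked which genes differ after transfection of the siRNA against KLF11, whose own level was not analysed here. Interferon-induced genes had the largest changes. CXCL10, a chemokine that draws T cells, was at least 7.97-fold higher (adjusted p = 8.37e-09) and RSAD2, the antiviral protein viperin, at least 4.87-fold higher (adjusted p = 1.67e-07). OAS2 (3.58 ± 0.32, adjusted p = 1.95e-06), a sensor of double-stranded RNA, and the antiviral GTPase MX1 (3.35 ± 0.33) rose. HERC5 (3.15 ± 0.25), detected on 2 of 3 control arrays, IFIT1 (2.93 ± 0.21), IFIT3 (2.92 ± 0.17), CCL8 (2.76 ± 0.15), OAS3 (2.67 ± 0.23) and IFI44L (2.67 ± 0.21) rose.

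AFF3 (-1.98 ± 0.29) and OMD (-1.56 ± 0.21), a proteoglycan of bone, fell and were each detected on 1 of 3 siKLF11 arrays. EFHD2 (-1.66 ± 0.11, adjusted p = 1.67e-07), a calcium-binding protein, SLC66A3 (-1.54 ± 0.08) and ISCA1 (-1.51 ± 0.15), which assembles iron-sulfur clusters, fell. PNMA1 (-1.49 ± 0.09), ATP5ME (-1.43 ± 0.08), a subunit of ATP synthase, and EEF2KMT (-1.40 ± 0.11), a methyltransferase of elongation factor 2, fell. PCP4 was at least 1.38-fold lower (adjusted p = 7.69e-06), and KANK4 (-1.34 ± 0.15) was detected on 2 of 3 siKLF11 arrays. Leaving out siKLF11 replicate 3 brought the count of called genes from 1419 to 870.

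Camera called 10 lists in siKLF11, of which 8 held with an estimated correlation. In the interferon response list of 42 genes, 40 rose and 0 fell, 41 and 0 adjusted over the list alone, with a median of 1.86 (1.68 with undetected genes at their bound), adjusted p = 1.32e-51 and adjusted p = 0.0125 with an estimated correlation. CXCL10, IFIT2 (2.13 ± 0.12), IFIT3 and the RNA sensor IFIH1 (2.46 ± 0.15) had the smallest p-values in it. In the NF-kB and inflammation list of 27 genes, 18 rose and 0 fell, 21 and 0 adjusted over the list alone, with a median of 0.77 (0.50 with undetected genes at their bound), adjusted p = 6.78e-16 and adjusted p = 0.00653 with an estimated correlation. CCL7 (2.23), CXCL8 (1.33) and CXCL2 (1.11) rose. In the replication histone list of 11 genes, 9 rose and 1 fell, 10 and 1 adjusted over the list alone, with a median of 0.77 (0.75 with undetected genes at their bound), adjusted p = 1.15e-10 and adjusted p = 0.00210 with an estimated correlation. H2AC6 (1.34) and H2BC5 (1.21) rose. In the metallothionein list of 8 genes, 6 rose and 0 fell, 8 and 0 adjusted over the list alone, with a median of 0.98 (0.65 with undetected genes at their bound), adjusted p = 2.66e-10 and adjusted p = 0.00280 with an estimated correlation. MT1M (1.07), MT1G (1.15) and MT1F (1.51), which bind zinc and copper, rose, and probes of these near-identical genes may cross-hybridise. In the HLA and antigen presentation list of 16 genes, 8 rose and 0 fell, 12 and 0 adjusted over the list alone, with a median of 0.46 (0.38 with undetected genes at their bound), adjusted p = 8.20e-08 and adjusted p = 0.0269 with an estimated correlation. PSMB9 (0.81) and PSMB8 (0.64), subunits of the immunoproteasome, rose.

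In the amino acid and ATF4 list of 28 genes, 0 rose and 10 fell, 1 and 15 adjusted over the list alone, with a median of -0.28, adjusted p = 2.53e-06 and adjusted p = 0.0127 with an estimated correlation. TRIB3 (-0.85) and ASNS (-0.54) fell. In the cholesterol biosynthesis list of 20 genes, 8 rose and 0 fell, 9 and 0 adjusted over the list alone, with a median of 0.29, adjusted p = 4.12e-05 and adjusted p = 0.0391 with an estimated correlation. DHCR7 (0.53) rose. In the glucocorticoid response list of 15 genes, 6 rose and 0 fell, 8 and 1 adjusted over the list alone, with a median of 0.21 (0.16 with undetected genes at their bound), adjusted p = 0.00809 and adjusted p = 0.0497 with an estimated correlation. ANGPTL4, the next member after MT1X (0.89), rose by 0.97 from 2 of 3 control arrays with a detected level. In the immediate early gene list of 23 genes, 9 rose and 0 fell, 11 and 2 adjusted over the list alone, with a median of 0.27, adjusted p = 0.000113 and adjusted p = 0.0550 with an estimated correlation. DUSP5 (0.72) and DUSP6 (0.95) rose. In the siRNA machinery list of 11 genes, 4 rose and 0 fell, 5 and 0 adjusted over the list alone, with a median of 0.25, adjusted p = 0.0200 and adjusted p = 0.0935 with an estimated correlation. TNRC6A (0.64), a partner of Argonaute proteins, rose on its brightest probe but did not pass on the mean of its probes (adjusted p = 0.141). The glucocorticoid call was lost without siCTRL replicate 3 (adjusted p = 0.0793). The siRNA machinery call in siKLF11 was lost without siCTRL replicate 3 (adjusted p = 0.0610) or with the mean of a gene's probes (adjusted p = 0.163). Among the genes named for siKLF11, ASNS (-0.38, adjusted p = 0.487), DHCR7 (0.57, adjusted p = 0.135) and TNRC6A (0.70, adjusted p = 0.0578) did not pass under median scaling. On lower-background arrays, with 1 array left in siKLF11, DHCR7 (0.41, adjusted p = 0.210) and KANK4 (-0.93, adjusted p = 0.0622) did not pass, nor did DHCR7 in a fit of the 2 groups compared (0.57, adjusted p = 0.0592).

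Against the other 4 siKLF groups, siKLF11 had 1245 genes set apart, 570 higher and 675 lower, and 761 without siKLF11 replicate 1 or 827 without siKLF11 replicate 3. MX1 (2.92 ± 0.26) stood above. CXCL10, detected on 9 of the 12 other arrays, was at least 7.58-fold higher (adjusted p = 2.05e-09) and RSAD2, detected on 3 of them, at least 6.32-fold higher (adjusted p = 8.84e-08). EFHD2 (-1.62 ± 0.09) and PNMA1 (-1.53 ± 0.07) stood below. The interferon response list had 40 of 42 genes higher and 0 lower, with a median of 1.41 (1.39 with undetected genes at their bound), adjusted p = 4.10e-65 and adjusted p = 0.0118 with an estimated correlation. The NF-kB and inflammation list had 14 of 27 genes higher and 0 lower, with a median of 0.35 (0.30 with undetected genes at their bound), adjusted p = 2.26e-10 and adjusted p = 0.0240 with an estimated correlation.

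In siKLF16, whose target KLF16 was below detection on all 18 arrays, the question was which genes differ after transfection of that siRNA. APOE, the lipid carrier apolipoprotein E, was at least 3.15-fold higher (adjusted p = 9.44e-08) and F13A1, a subunit of clotting factor XIII, at least 1.57-fold higher (adjusted p = 3.23e-06). MMP9 (2.18 ± 0.09, adjusted p = 6.65e-10), a protease that degrades gelatin and collagen, and CCL7 (2.06 ± 0.13) rose. KYNU, an enzyme that breaks down kynurenine, was at least 1.87-fold higher (adjusted p = 2.34e-05).

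Among the lowest genes in siKLF16, B3GALT2 was at least 2.26-fold lower (adjusted p = 6.87e-07). EIF2S2 (-1.79 ± 0.12), a subunit of translation initiation factor 2, fell, and so did PTX3 (-1.66 ± 0.18), a secreted pattern recognition protein, and NUDCD1 (-1.58 ± 0.11), the last 2 detected on 2 of 3 siKLF16 arrays. GALNT16 was at least 2.41-fold lower (adjusted p = 1.40e-06) and the phosphodiesterase PDE1C at least 2.13-fold lower (adjusted p = 0.00173). KCNH1 (-1.56 ± 0.14), MRS2 (-1.54 ± 0.11), a mitochondrial magnesium channel, IGFBP3 (-1.53 ± 0.11), which binds insulin-like growth factors, and FAM171A1 (-1.46 ± 0.08) fell.

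Camera called 16 lists in siKLF16, of which 6 held with an estimated correlation. In the G2/M and mitosis list of 54 genes, 1 rose and 33 fell, 1 and 41 adjusted over the list alone, with a median of -0.43, adjusted p = 2.24e-13 and adjusted p = 0.142 with an estimated correlation. MELK (-0.73 ± 0.08), a mitotic kinase, fell while CDC25B (0.66) rose. In the S-phase replication list of 39 genes, 0 rose and 21 fell, 0 and 24 adjusted over the list alone, with a median of -0.46 (-0.36 with undetected genes at their bound), adjusted p = 8.91e-11 and adjusted p = 0.0391 with an estimated correlation. GINS2 (-1.09) and CDC45 (-0.84), parts of the replicative helicase, and CHAF1B (-1.03), which deposits histones on new DNA, fell. In the amino acid and ATF4 list of 28 genes, 1 rose and 19 fell, 2 and 21 adjusted over the list alone, with a median of -0.40, adjusted p = 1.78e-09 and adjusted p = 0.00558 with an estimated correlation. PCK2 (-0.98), CTH (-0.82) and TRIB3 (-0.79) fell. In the NF-kB and inflammation list of 27 genes, 17 rose and 2 fell, 20 and 2 adjusted over the list alone, with a median of 0.65 (0.48 with undetected genes at their bound), adjusted p = 9.66e-09 and adjusted p = 0.0300 with an estimated correlation. CXCL8 (1.72 ± 0.10) rose. In the metallothionein list of 8 genes, 6 rose and 0 fell, 7 and 0 adjusted over the list alone, with a median of 0.91 (0.57 with undetected genes at their bound), adjusted p = 1.61e-06 and adjusted p = 0.00770 with an estimated correlation. MT1M (1.06) and MT1G (1.04) rose. In the interferon response list of 42 genes, 19 rose and 1 fell, 26 and 2 adjusted over the list alone, with a median of 0.55 (0.43 with undetected genes at their bound), adjusted p = 2.04e-06 and adjusted p = 0.443 with an estimated correlation. CXCL10 was at least 1.14-fold higher (adjusted p = 0.000624), and IFIT3 (0.97) rose.

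In the replication histone list of 11 genes, 8 rose and 1 fell, 10 and 1 adjusted over the list alone, with a median of 0.46 (0.44 with undetected genes at their bound), adjusted p = 3.31e-06 and adjusted p = 0.00653 with an estimated correlation. H2BC5 (1.03) and H2AC6 (0.94) rose. In the HLA and antigen presentation list of 16 genes, 8 rose and 0 fell, 11 and 0 adjusted over the list alone, with a median of 0.42 (0.34 with undetected genes at their bound), adjusted p = 1.91e-05 and adjusted p = 0.0645 with an estimated correlation. PSMB9 (0.97) and HLA-B (0.84) rose. In the matrix protease list of 19 genes, 10 rose and 1 fell, 12 and 3 adjusted over the list alone, with a median of 0.39 (0.34 with undetected genes at their bound), adjusted p = 0.00159 and adjusted p = 0.0715 with an estimated correlation. TIMP3 (1.08), an inhibitor of these proteases, and the collagenase MMP1 (1.34) rose. In the myofibroblast and smooth muscle list of 12 genes, 0 rose and 4 fell, 0 and 5 adjusted over the list alone, with a median of -0.24, adjusted p = 0.00527 and adjusted p = 0.186 with an estimated correlation. TAGLN (-0.76) fell. The myofibroblast call in siKLF16 was lost under median scaling (median -0.12, adjusted p = 0.292). In the p53 target list of 24 genes, 6 rose and 0 fell, 7 and 0 adjusted over the list alone, with a median of 0.21, adjusted p = 0.00750 and adjusted p = 0.0445 with an estimated correlation. BAX (1.24) and SESN1 (0.68) rose.

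In the lysosome and autophagy list of 25 genes, 4 rose and 0 fell, 4 and 0 adjusted over the list alone, with a median of 0.17, adjusted p = 0.0209 and adjusted p = 0.121 with an estimated correlation. NEU1 (0.59), a lysosomal sialidase, rose. In the epithelial and keratinocyte marker list of 5 genes, 0 rose and 3 fell, 0 and 3 adjusted over the list alone, with a median of -0.67 (-0.21 with undetected genes at their bound), adjusted p = 0.0211 and adjusted p = 0.0952 with an estimated correlation. DSP (-0.67), a desmosome protein, fell. The epithelial marker call was lost without a detection filter (median -0.17, adjusted p = 0.0780). In the immediate early gene list of 23 genes, 7 rose and 1 fell, 7 and 2 adjusted over the list alone, with a median of 0.20, adjusted p = 0.0343 and adjusted p = 0.285 with an estimated correlation. EGR1 (0.80) and DUSP6 (0.81) rose. In the neural marker list of 8 genes, 3 rose and 0 fell, 3 and 0 adjusted over the list alone, with a median of 0.28 (0.10 with undetected genes at their bound), adjusted p = 0.0379 and adjusted p = 0.197 with an estimated correlation. NEFM (1.64), detected on 2 of 3 control arrays, rose. In the osteogenesis list of 10 genes, 3 rose and 1 fell, 4 and 1 adjusted over the list alone, with a median of 0.29 (0.08 with undetected genes at their bound), adjusted p = 0.0442 and adjusted p = 0.321 with an estimated correlation. BMP2 (1.25), a bone morphogenetic protein, rose. The lysosome call was lost without siCTRL replicate 1 (adjusted p = 0.148). The immediate early call in siKLF16 was lost without siCTRL replicate 2 (adjusted p = 0.0798), without siCTRL replicate 3 (adjusted p = 0.0539), without siKLF16 replicate 1 (adjusted p = 0.0763), under median scaling (adjusted p = 0.0622) or with a background covariate (median 0.13, adjusted p = 0.0542). The neural marker call in siKLF16 was lost without siCTRL replicate 2 (median 0.14, adjusted p = 0.0592), without siCTRL replicate 3 (median 0.43, adjusted p = 0.0539) or without siKLF16 replicate 1 (adjusted p = 0.0581). The osteogenesis call was lost without siCTRL replicate 2 (adjusted p = 0.117), without siCTRL replicate 3 (adjusted p = 0.0539), without siKLF16 replicate 1 (adjusted p = 0.101), with probes detected on all 18 arrays (median 0.14, adjusted p = 0.0610), with array weights (adjusted p = 0.0577), with a background covariate (adjusted p = 0.0856) or on lower-background arrays (adjusted p = 0.0679). Among the genes named for siKLF16, CDC25B (0.68, adjusted p = 0.0615), TAGLN (-0.46, adjusted p = 0.273) and DSP (-0.61, adjusted p = 0.0557) did not pass under median scaling.

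Against the other 4 siKLF groups, siKLF16 had 2052 genes set apart, 1044 higher and 1008 lower. APOE, detected on 5 of the 12 other arrays, was at least 3.60-fold higher (adjusted p = 1.47e-07), F13A1 was at least 2.06-fold higher (adjusted p = 3.00e-06) and MMP9 (1.47 ± 0.07) was higher. MRS2 (-1.63 ± 0.08) stood below, and the neuronal pentraxin NPTX1 was at least 2.41-fold lower (adjusted p = 1.54e-05). The G2/M and mitosis list had 0 of 54 genes higher and 45 lower, with a median of -0.51, adjusted p = 5.26e-27 and adjusted p = 0.0391 with an estimated correlation. The S-phase replication list had 1 of 39 genes higher and 25 lower, with a median of -0.50 (-0.47 with undetected genes at their bound), adjusted p = 2.55e-16 and adjusted p = 0.0226 with an estimated correlation.

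In siKLF17, whose target KLF17 was below detection on all 18 arrays, the same question was asked. SNCG, gamma-synuclein, was at least 1.57-fold higher (adjusted p = 6.91e-05). IGF2BP3 (1.90 ± 0.14) rose and was detected on 1 of 3 control arrays. IQUB (1.87 ± 0.45, adjusted p = 0.0118) was detected on 1 of 3 control arrays and did not pass without siCTRL replicate 2 (1.40, adjusted p = 0.0553). MAMDC2 (1.83 ± 0.26) and the integrin ITGA3 (1.69 ± 0.17) rose and were detected on 2 of 3 control arrays. IL7R (1.76 ± 0.16, adjusted p = 6.86e-06), the interleukin-7 receptor, rose. NOTUM, which inactivates Wnt proteins, was at least 1.36-fold higher (adjusted p = 0.000130). ADAMTSL2 (1.67 ± 0.26) and the transcription factor FOXS1 (1.63 ± 0.25) were detected on 1 of 3 control arrays and HTR2B (1.55 ± 0.12), a serotonin receptor, on 2 of 3.

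PCP4 was at least 1.40-fold lower in siKLF17 (adjusted p = 1.66e-06). RASD1 (-1.68 ± 0.13), a Ras-like protein induced by glucocorticoids, PRG4 (-1.60 ± 0.12), RASIP1 (-1.39 ± 0.11) and MASP1 (-1.35 ± 0.11), a protease of the lectin complement pathway, fell. IL1RN, the interleukin-1 receptor antagonist, was at least 1.40-fold lower (adjusted p = 0.000209), CEL at least 2.36-fold (adjusted p = 0.000209) and MMP27 at least 1.85-fold (adjusted p = 1.63e-06). HSD17B6 was at least 1.43-fold lower (adjusted p = 0.000309) and KLF3-AS1 at least 1.08-fold lower (adjusted p = 0.00583). The count of 1554 called genes went to 987 without siCTRL replicate 2, 975 without siKLF17 replicate 3 and 1003 without siKLF17 replicate 2.

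Camera called 9 lists in siKLF17, of which 2 held with an estimated correlation. In the G2/M and mitosis list of 54 genes, 13 rose and 0 fell, 18 and 0 adjusted over the list alone, with a median of 0.23, adjusted p = 6.19e-07 and adjusted p = 0.330 with an estimated correlation. CDC25B (0.68) rose. In the interferon response list of 42 genes, 12 rose and 0 fell, 18 and 1 adjusted over the list alone, with a median of 0.36 (0.30 with undetected genes at their bound), adjusted p = 1.61e-06 and adjusted p = 0.439 with an estimated correlation. CXCL10 was at least 1.15-fold higher (adjusted p = 0.000900), and IFIT3 (0.94) and IFITM1 (0.90) rose. In the HLA and antigen presentation list of 16 genes, 5 rose and 0 fell, 7 and 0 adjusted over the list alone, with a median of 0.29 (0.26 with undetected genes at their bound), adjusted p = 0.000570 and adjusted p = 0.136 with an estimated correlation. PSMB9 (0.64) rose. In the mesenchymal stem marker list of 16 genes, 5 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median of 0.22, adjusted p = 0.00110 and adjusted p = 0.0479 with an estimated correlation. NT5E (0.62), the surface antigen CD73, and the adhesion molecule VCAM1 (0.83) rose. In the cholesterol biosynthesis list of 20 genes, 6 rose and 0 fell, 8 and 0 adjusted over the list alone, with a median of 0.23, adjusted p = 0.00128 and adjusted p = 0.0935 with an estimated correlation. MSMO1 (0.53) rose.

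In the glycolysis and hypoxia list of 36 genes, 8 rose and 2 fell, 9 and 2 adjusted over the list alone, with a median of 0.15, adjusted p = 0.00128 and adjusted p = 0.0163 with an estimated correlation. ANGPTL4 (1.34), detected on 2 of 3 control arrays, and the glucose transporter SLC2A3 (0.78) rose. In the siRNA machinery list of 11 genes, 6 rose and 0 fell, 7 and 1 adjusted over the list alone, with a median of 0.35, adjusted p = 0.00623 and adjusted p = 0.0549 with an estimated correlation. TNRC6A (0.59) and DICER1 (0.52), which cuts double-stranded RNA, rose. In the metallothionein list of 8 genes, 3 rose and 0 fell, 4 and 0 adjusted over the list alone, with a median of 0.31 (0.13 with undetected genes at their bound), adjusted p = 0.0220 and adjusted p = 0.121 with an estimated correlation. MT1G (0.61) rose. In the chondrogenesis list of 8 genes, 0 rose and 3 fell, 0 and 3 adjusted over the list alone, with a median of -0.20, adjusted p = 0.0240 and adjusted p = 0.149 with an estimated correlation. PRG4 and SOX9 (-0.60), the master regulator of cartilage, fell. The chondrogenesis call in siKLF17 was lost without siCTRL replicate 3 (adjusted p = 0.0546), without siKLF17 replicate 3 (adjusted p = 0.0592) or without a detection filter (median -0.07, adjusted p = 0.112). Among the genes named for siKLF17, CDC25B (0.75, adjusted p = 0.0534), NT5E (0.73, adjusted p = 0.0636), MSMO1 (0.62, adjusted p = 0.134), TNRC6A (0.66, adjusted p = 0.0874), DICER1 (0.59, adjusted p = 0.111), MT1G (0.70, adjusted p = 0.0636) and SOX9 (-0.53, adjusted p = 0.141) did not pass under median scaling.

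Against the other 4 siKLF groups, siKLF17 had 2761 genes set apart, 1364 higher and 1397 lower, and 1831 without siKLF17 replicate 2. FOXS1, detected on 4 of the 12 other arrays, was at least 2.94-fold higher (adjusted p = 3.06e-06). ADAMTSL2 was at least 2.39-fold higher (adjusted p = 3.43e-05) and ANKRD1 at least 1.94-fold higher (adjusted p = 1.02e-07), each detected on 1 of the 12. IL1RN was at least 2.39-fold lower (adjusted p = 1.36e-07) and FOXQ1 at least 1.76-fold lower (adjusted p = 2.68e-07). BMP2 (-1.90 ± 0.09), RASD1 (-1.63 ± 0.10) and CXCL8 (-1.58 ± 0.08) stood below. The amino acid and ATF4 list had 20 of 28 genes higher and 0 lower, with a median of 0.42, adjusted p = 5.47e-10 and adjusted p = 0.00557 with an estimated correlation. Against siCTRL that list was not called in siKLF17 (median 0.07). The glycolysis and hypoxia list had 13 of 36 genes higher and 2 lower, with a median of 0.16, adjusted p = 0.00203 and adjusted p = 0.0240 with an estimated correlation.

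**Figure D3:**
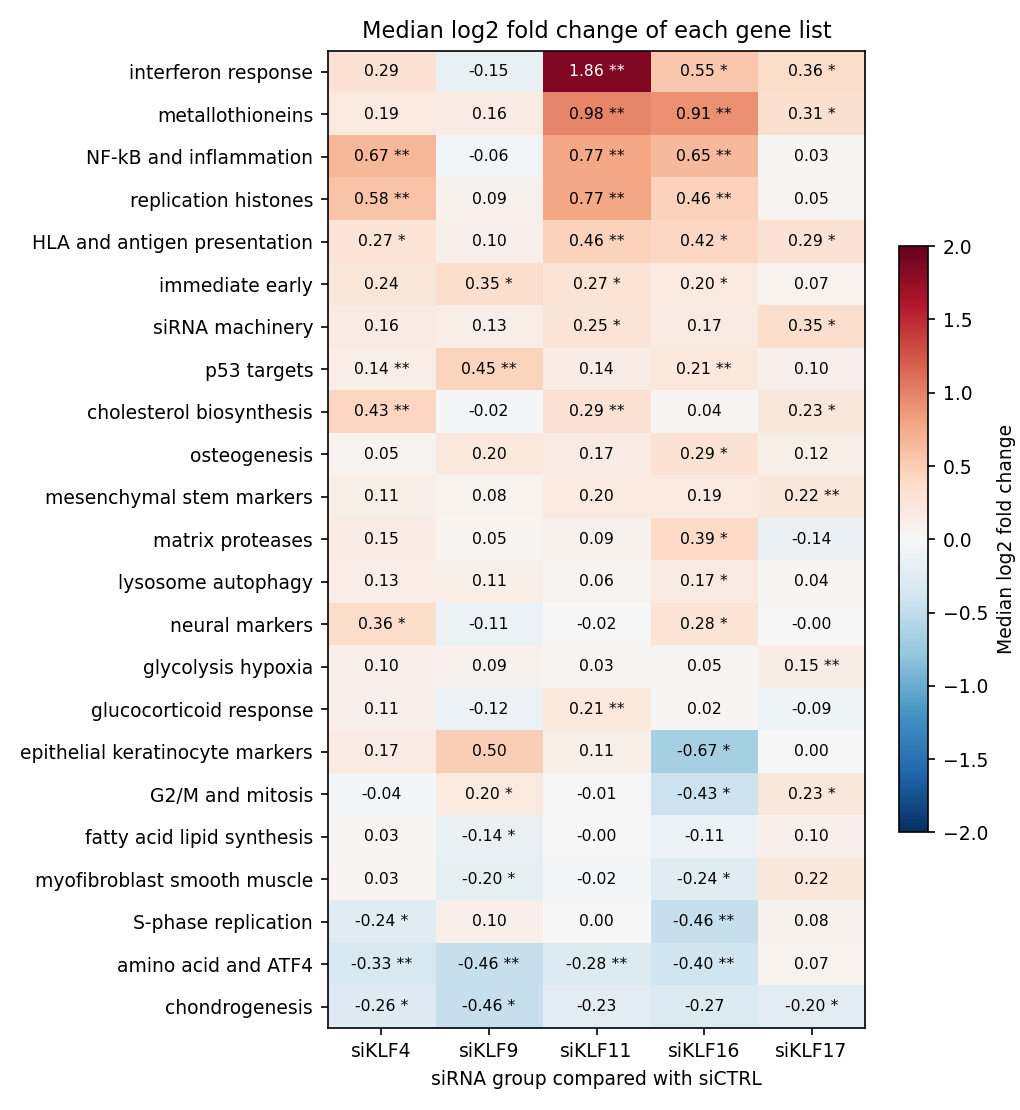
Median log2 fold change of each gene list called in at least 1 comparison, by siKLF group against siCTRL; * marks lists past camera adjusted p under 0.05 with the preset correlation and ** those past it with an estimated correlation too. The interferon response list had a median of 1.86 in siKLF11 and -0.15 in siKLF9.

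The last question was how far the knockdowns resembled each other. The moderated F test called 6171 of 11255 genes (54.8%) as differing among the 6 groups. Of 6015 genes called in any comparison with siCTRL, 2984 were called in 1 only. In the order siKLF4, siKLF9, siKLF11, siKLF16 and siKLF17, the log2 fold changes of GJB2 were -1.17, 1.33, 1.03, 0.41 and 0.36, and each passed. Those of CCL7 were 2.35, 0.89, 2.23, 2.06 and 1.47, and each passed. MMP9 had 0.66, 0.11, 1.35, 2.18 and 0.73, and siKLF9 did not pass (adjusted p = 0.368). CXCL8 had 1.69, 0.65, 1.33, 1.72 and -0.23, and RAB27B, a regulator of vesicle secretion, had 0.97, 0.94, 0.86, 1.56 and -0.23, with siKLF17 not passing for either (adjusted p = 0.125 and 0.0994). Without siKLF17 replicate 1 CXCL8 passed as lower in siKLF17 (-0.34, adjusted p = 0.0320), and without siCTRL replicate 3 RAB27B did (-0.31, adjusted p = 0.0340). CXCL10 was detected on 0 of 3 control arrays and 0 of 3 siKLF9 arrays, and was at least 1.23-fold higher in siKLF4 (adjusted p = 0.000205).

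The transporter ABCC3 had 0.99, -0.92, 0.43, 0.88 and 0.94, lower in siKLF9 and higher elsewhere. BMP2 had 1.36, 0.93, 0.44, 1.25 and -0.90, lower in siKLF17 and higher elsewhere. The BMP2 call in siKLF11 was lost without siCTRL replicate 3 (adjusted p = 0.0751), siKLF11 replicate 2 (0.0720) or siKLF11 replicate 3 (0.0655). PCP4 was lower in siKLF4, siKLF11 and siKLF17 as above and in siKLF16 (-0.73, detected on 1 of 3 arrays). It did not pass in siKLF9 (0.34, adjusted p = 0.0912), where it passed as higher without siCTRL replicate 2 (0.45, adjusted p = 0.0445) or siKLF9 replicate 3 (0.45, adjusted p = 0.0418). Under median scaling, GJB2 in siKLF16 (0.49, adjusted p = 0.128) and siKLF17 (0.45, adjusted p = 0.220), and ABCC3 (0.50, adjusted p = 0.191) and BMP2 (0.52, adjusted p = 0.183) in siKLF11 did not pass. In a fit of the 2 groups compared, GJB2 in siKLF17 (0.37, adjusted p = 0.0707), ABCC3 (0.43, adjusted p = 0.0537) and BMP2 (0.45, adjusted p = 0.0865) in siKLF11 did not pass. On lower-background arrays, with 1 array left in siKLF11, neither ABCC3 (0.33, adjusted p = 0.417) nor BMP2 (0.62, adjusted p = 0.127) did there.

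**Figure D4:**
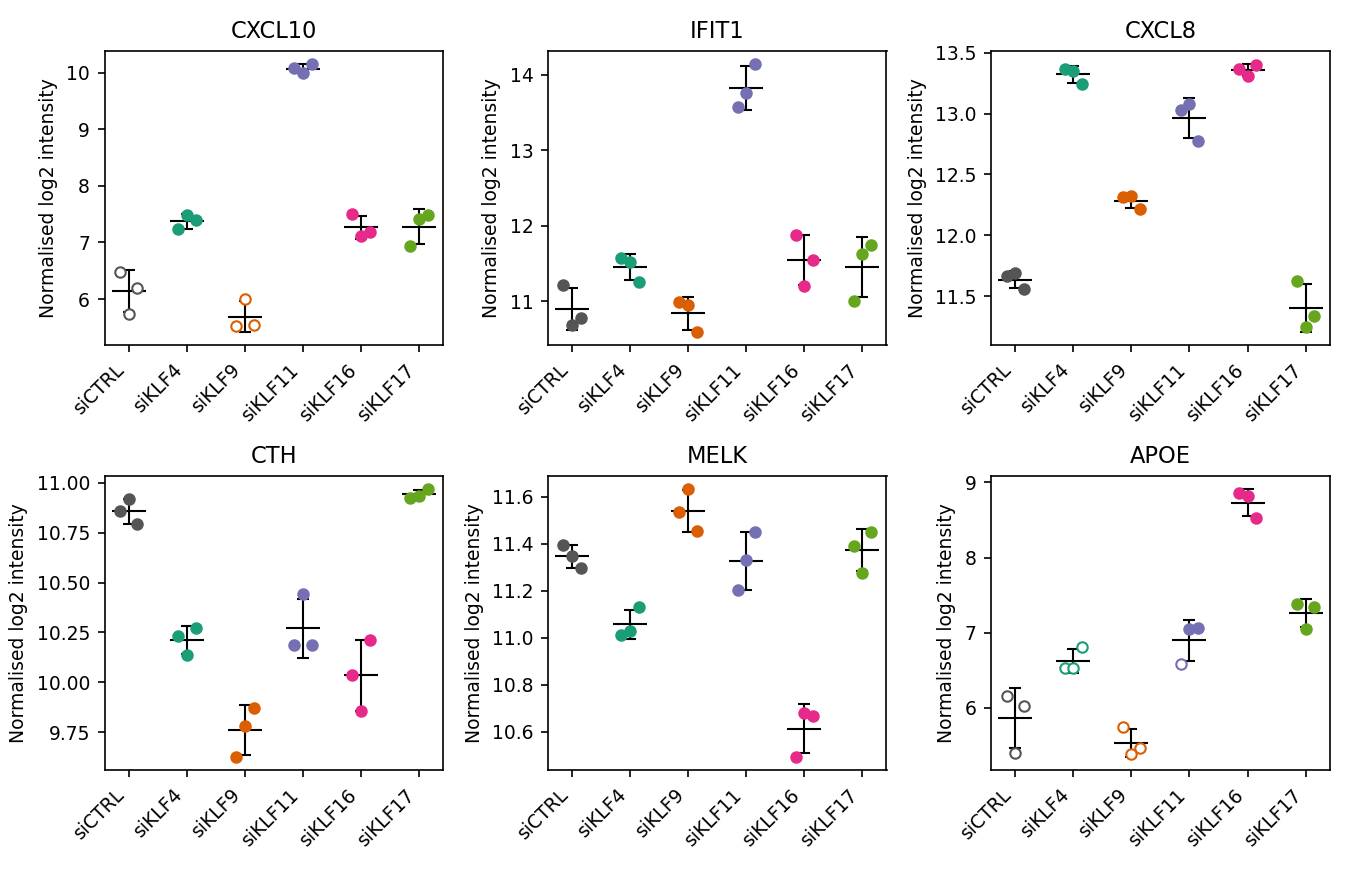
Normalised log2 intensity of CXCL10, IFIT1, CXCL8, CTH, MELK and APOE on each of the 18 arrays, by group; filled points are arrays on which the probe was detected, open points arrays on which it was not, and bars give the group mean and the SD of 3 arrays. CXCL10 was detected on 0 of 3 control arrays and stood highest in siKLF11. CTH fell in siKLF4, siKLF9, siKLF11 and siKLF16, and MELK fell in siKLF16 (-0.73). Under median scaling CTH did not pass in siKLF4 (-0.52, limma adjusted p = 0.0974) or siKLF11 (-0.55, limma adjusted p = 0.149). On lower-background arrays, with 1 array left in siKLF11, CTH in siKLF11 stood at -0.39, against -0.59 with all arrays.

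In total, 458 genes were called in the same direction in at least 4 of the 5 comparisons, 264 higher and 194 lower, and 69 rose and 38 fell in all 5. The siKLF groups share their control arrays, which alone makes their changes alike. In 100 simulations of unchanged groups sharing 3 controls, that count averaged 0.01 and reached 1 at most, and independent lists of the same sizes would share 4.8 higher and 4.0 lower. The simulations leave out real effects and independent lists leave out the shared controls, so the excess over either is not shown to be a shared effect, and part of it may come from the controls. Without siCTRL replicate 2 it was 279, of which 243 were among the 458, and without siCTRL replicate 3 it was 788. The siKLF4 and siKLF16 comparisons shared 637 higher and 488 lower genes, where independent lists would share 164.5 and 128.3, and 79 went opposite ways. Log2 fold changes correlated across genes, which are not independent replicates, at 0.32 for siKLF9 with siKLF17 to 0.60 for siKLF4 with siKLF16, all below the 0.656 to 0.693 of the simulations. Their covariances, 0.0367 to 0.0759, exceeded the 0.0215 to 0.0216 of these simulations, in which genes vary independently of each other. Without siCTRL replicate 2 the covariances were 0.0234 to 0.0633, against a simulated 0.0210 to 0.0211. The lowest, siKLF9 with siKLF17, went from 0.0367 to 0.0234, close to the simulated value. Leaving out that array lowered every covariance in the data by more than it lowered the simulated ones. The simulations may therefore understate what the shared controls bring, and the excess does not measure a shared effect.

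The adipogenesis and collagen matrix lists were among those that no comparison called. In the adipogenesis list of 18 genes, 4 rose and 2 fell in siKLF4, 1 and 4 in siKLF9, 4 and 2 in siKLF11, 1 and 1 in siKLF16, and 3 and 0 in siKLF17. Camera gave it adjusted p = 0.812, 0.213, 0.612, 0.872 and 0.438 in that order. The collagen matrix list of 32 genes had adjusted p = 0.676, 0.338, 0.169, 0.973 and 0.936. The housekeeping list of 12 genes had medians of 0.01, 0.04, 0.03, -0.01 and 0.10 and was not called, with adjusted p = 0.902, 0.973, 0.837, 0.984 and 0.562.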

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

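The tests of siKLF17 against the noisy control array and the shared controls, and that of the interferon genes against transfection of any siRNA, were chosen only after the results were seen.

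Probes without a single gene name took no part in the comparisons of genes, and some differed from the control arrays. Of 4010 such probes, 524 were called in siKLF4 (246 higher and 278 lower), 657 in siKLF9 (364 and 293), 275 in siKLF11 (158 and 117), 463 in siKLF16 (259 and 204) and 378 in siKLF17 (180 and 198). Named genes, each taken at its brightest probe, were called at higher shares, 24.8%, 27.1%, 12.6%, 20.9% and 13.8% in that order. Probe ILMN_1681515 fell by 3.84 on the log2 scale in siKLF9 (limma adjusted p = 4.93e-08), and ILMN_1751656 fell by 2.03 in siKLF11 (limma adjusted p = 8.90e-09). Probe ILMN_3253126 rose by 2.06 in siKLF9 and ILMN_1651610 by 1.87 in siKLF4. Which transcripts these probes measure was not settled with the annotation used, and no explanation was tested.

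In siKLF17, 1554 genes were called although KLF17 itself was not detected on any array. The noisy control array does not account for all of it, since 987 genes were called without it. Error in the shared controls as a whole would move all 5 comparisons alike. As the only cause it is argued against for 301 genes, called in siKLF17 alone and set apart from the other 4 in the same direction. They numbered 189, 172 and 161 without siKLF17 replicate 1, 2 or 3, and 65 under median scaling. These genes were picked by those calls, so control error may still add to their difference from siCTRL. It is also argued against as the only cause for those of the other 1253 called the opposite way in another comparison. These numbered 120 with siKLF4, 167 with siKLF9, 38 with siKLF11 and 125 with siKLF16, with overlap possible. For the rest it stays open. Loss of another KLF family member is argued against only for the 8 tested. Their lowest log2 fold change in siKLF17 was -0.21, for KLF9 (limma adjusted p = 0.0905). KLF2 (0.37, limma adjusted p = 0.0221) and KLF6 (0.38, limma adjusted p = 0.0408) were higher there. KLF1, KLF5, KLF7, KLF8, KLF14, KLF15 and KLF16 were detected on no array, and KLF11 had no probe under that name. A loss of any of these could not be seen and stays open. The argument from the 8 tested members does not hold for siKLF16, whose target was not detected either. There KLF2 was lower (-0.88, limma adjusted p = 1.79e-05) and KLF13 higher (0.46, limma adjusted p = 0.00624). Expression of KLF17 below the detection limit, effects of the siRNA on other transcripts, and a technical difference between the groups stay open, since the siRNA sequences were not used here and no batch is given.

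Interferon response genes rose in siKLF11, with a median of 1.86, and 39 of 42 still rose without siCTRL replicate 2. White blood cells in those cultures would bring all their abundant transcripts. The 6 leukocyte markers tested had a median of 0.17, PTPRC, CD74 and LYZ were detected on no siCTRL or siKLF11 array, and CD14 on 0 of 3 and 1 of 3. CSF1R (0.96, limma adjusted p = 0.00784) and CD68 (0.31, limma adjusted p = 0.0381) were higher, but both were detected on control arrays too (1 of 3 and 3 of 3). Transfection of any siRNA would act alike in siCTRL, which received a scrambled one, and in all siKLF groups, but the list stood 1.41 higher in siKLF11 than in the other 4 (1.39 with undetected genes at their bound). Sensing of that siRNA by innate immunity, which depends on its sequence and preparation, and an effect of lower KLF11 both stay open, and these data do not separate them.

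The amino acid and ATF4 list fell in siKLF4, siKLF9, siKLF11 and siKLF16. High values of that list in the shared control arrays alone would lower it in all 5 comparisons, but its median in siKLF17 was 0.070. Without siCTRL replicate 2, the list was called lower in 4 of the 4 comparisons. In siKLF17 it stood 0.42 above the other knockdowns. High control values together with a rise of the list in siKLF17 would give the same pattern, and that stays open. A difference in medium, density or growth between the wells of these groups stays open, as does an effect shared by the 4 knockdowns.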

How the results depend on the processing

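The fits on lower-background arrays and with a background covariate were chosen after the data were seen. Of 389 gene results, called or not, 97 lost their call under at least 1 alternative other than leaving out arrays, and of 51 list calls 10 did. With each result counted once per alternative, 4298 for genes kept their side of the threshold, 189 were lost, 2 were gained and 3 reversed, and 538 for lists stayed and 20 were lost. Median scaling cost 85 gene calls, lower-background arrays 43 and a fit on 2 groups 38. Leaving out 1 array ended 21 of the gene calls and 12 of the list calls at least once (counted once per array, 2702 for genes kept, 54 lost and 8 gained, and 282 for lists kept and 23 lost). The reversed values, under median scaling, were CALD1 in siKLF9 (0.044, limma adjusted p = 0.936) and in siKLF16 (0.17, limma adjusted p = 0.776), and CD151 in siKLF17 (0.18, limma adjusted p = 0.800). The cause was not tested.

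Counts for siKLF4, siKLF9, siKLF11, siKLF16 and siKLF17 are given in that order. Against siCTRL, median scaling gave 994, 1062, 339, 521 and 269 genes, a fit on the 2 groups compared, with fewer arrays, 1449, 1749, 471, 1112 and 496, and a minimum of 1.5-fold, stricter by construction, 962, 1087, 542, 776 and 522. Lower-background arrays, with 11 arrays and 1 array each for siKLF9 and siKLF11, assumed to vary like the other groups, gave 1604, 974, 285, 1239 and 980. Genes set apart numbered 783, 1357, 280, 473 and 704 under median scaling, and on lower-background arrays 1618 in siKLF4, 1369 in siKLF9, 222 in siKLF11 and 1243 in siKLF16. The F test called 2515 genes under median scaling and 3737 on lower-background arrays. Genes shared by at least 4 comparisons numbered 74 under median scaling, 292 without a detection filter, 292 with array weights and 102 on lower-background arrays. Median scaling called 14 lists in siKLF17. For median scaling, array weights and the detection filter, the cause was not tested.

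Leaving out 1 array gave 870 to 1737 genes in siKLF11, lowest without siKLF11 replicate 3, and 975 to 1968 in siKLF17, lowest without siKLF17 replicate 3. Genes set apart ranged from 761 to 1183 in siKLF11 and from 1831 to 2740 in siKLF17, and shared genes from 279 without siCTRL replicate 2 to 788 without siCTRL replicate 3. The other counts stayed within 1.5 times, at 2046 to 3035 in siKLF4, 2165 to 3107 in siKLF9, 1676 to 2722 in siKLF16 and 5602 to 6514 for the F test. KLF4 in siKLF4 ranged from -2.08 to -1.90 and KLF9 in siKLF9 from -2.50 to -2.35.

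The replicate number as a block gave 2703, 2956, 1347, 2271 and 1481 genes, and 1 named gene call was lost, KLF4 in siKLF11 (limma adjusted p = 0.0534). Replicate numbers did not pair the arrays, since 7 of 18 arrays correlated best with their own number across groups. Signal over background limits what low genes can show. On siCTRL replicate 2, 13962 probes were detected against 16913 to 18145 elsewhere. Genes undetected on all 3 control arrays are given as bounds. KLF16 and KLF17 lay below detection on all 18 arrays.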

Other observations

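The counts of other splits of the arrays below were planned. For each siKLF group against siCTRL the 6 arrays allow 10 splits, which cannot give a share under 0.05. The real split called 2795 genes in siKLF4 and the highest other 0, 3054 and 2 in siKLF9, 1419 and 1 in siKLF11, 2352 and 0 in siKLF16, and 1554 and 1 in siKLF17. Called lists numbered 9 and at most 8 in another split in siKLF4, 7 and 5 in siKLF9, 10 and 8 in siKLF11, 16 and 10 in siKLF16, and 9 and 6 in siKLF17. Mixed splits thus came near the real number of lists in siKLF4, siKLF9 and siKLF11. The number of lists called there is therefore not shown to come from the siRNA.

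Where more splits were possible, 100 were compared, and the real split gave the highest count each time, a share of 1 of 100 for each count. For the F test, that argues against an accidental grouping of the arrays. It cannot tell an effect of the siRNA from a technical difference shared by the 3 arrays of a group. For the genes set apart, the other splits also mixed the remaining siKLF groups, which adds their differences to the spread. The real split is thereby favoured for every group, so those shares decide nothing about a single group. The F test called 6171 genes against at most 100 in another split. By at least 4 comparisons 458 genes were shared against 0, which follows from the few calls those splits made and does not show that the responses are alike. Genes set apart from the other siKLF groups numbered 2539 against at most 49 in siKLF4, 3541 against 57 in siKLF9, 1245 against 888 in siKLF11, 2052 against 2001 in siKLF16 and 2761 against 710 in siKLF17. The splits with 888 and 710 put the 3 siKLF4 arrays together, and the split with 2001 put the 3 siKLF9 arrays together, so they follow another real group.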
